A study of Mus musculus with 6 samples.

How the data were processed

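The series holds 6 single-cell libraries (10x 3' v3.1) of sorted liver cells, 1 for each of control, caMEK1 and caMKK6 mice and each of the colours mCherry and GFP, taken on day 7 of doxycycline per the labels. Per the labels' protocols, hepatocytes were isolated by collagenase perfusion and low-speed spins and sorted on colour, with dead cells gated out. The protocol says that cells from 3 mice were loaded, without saying whether this holds for each library. The deposited matrices hold UMI counts per gene and barcode, with whole numbers in every entry. Cell Ranger 4.0.0 and the genome build mm10 are named in the submitters' processing notes. The 32289 features included 4 added sequences: mCherry, EGFP, human MKK6 and Xenopus MEK1. Of the feature identifiers, 32158 were found in the mm10 annotation used here for coordinates, GENCODE vM21. Groups were taken from the sample titles.

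Cells with at least 1000 UMIs, 500 genes and at most 30% of UMIs from mitochondrial genes were kept. This left 977, 663, 2364, 1996, 3808 and 1473 of the 14003 barcodes, in the order control, caMEK1 and caMKK6 with mCherry before GFP. The cells with the highest Scrublet scores, 0.8% per 1000 cells of a library, were left out as doublets. The other 11059 cells were normalized to 10000 UMIs and log-transformed. They were clustered together without integration on 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1. Of 25 clusters, 12 were hepatocyte-like.

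A cluster took the name of the eligible marker set with the highest mean score over the markers with a UMI in any cluster. A marker counted as detected from 10% of the cluster's cells, and a set was eligible with 3 detected markers. A name other than hepatocyte needed a marker of its own among the 10 leading genes. How this rule was read was settled after the clusters, but not the folds, had been seen. The other reading, with the mean over detected markers only, is among the added alternatives. Clusters with a median UMI count under 1/3 of that of their libraries and no marker of their best-scoring eligible set among these leading genes stayed unnamed. An unnamed cluster with hepatocyte and endothelial genes held 1.38% (0.946 to 1.94) of caMEK1 mCherry and 9.62% (8.35 to 11.01) of caMEK1 GFP cells and none of the other libraries' cells.

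UMIs of the hepatocyte-like cells were summed per library and given as CPM, that is, scaled to the total of that sum. With 1 library per group no group has a spread of its own and no test was run, so values are given for 9 pairs of libraries. Intervals of CPM are exact Poisson and those of folds exact conditional binomial 95% intervals, and shares of cells have exact binomial intervals. All of them cover counting error only. Log2 folds use CPM plus 1. At the depth of the smallest sum, 9756915 UMIs, 3 UMIs correspond to 0.307 CPM. For shares of cells with a UMI, cells were thinned to 2000 UMIs, and where an unthinned share is given, the thinned share is given beside it or the cells are called unthinned. TMM factors, from edgeR 4.0.16, were 1.15, 1.24, 0.809, 0.827, 0.981 and 1.07.

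The 38 gene lists, the markers, the comparisons, the thresholds and the rule for named genes were set before the data were examined. Some lists share members. Lcn2 is in both the SASP and the acute phase list, and Areg, Ereg and Hbegf are in both the SASP and the ERK list. Slco1a1 and Cyp7b1 are in both the bile acid and the male-biased list. List medians cover members at 10 CPM or more in either library. Random lists were drawn from 20 bins of expression. Per comparison, the rule named the 10 highest and 10 lowest genes at 20 CPM or more whose interval excluded 1, leaving out mitochondrial, ribosomal, hemoglobin, immunoglobulin and predicted genes. It also named up to 4 members of each list by size of fold, and Map2k1, Map2k6, Cdkn1a, Cdkn2a, Cdkn2b and Gdf15. Some of the genes that the rule names are not reported here. Ddit3, Mx1 and Mx2 matched no feature, and Aldoa matched 2 and was left out. Copies of families such as Saa, Orm, Mup, Cyp2c, Cyp3a and Serpina1 share sequence, so the split of reads among their members is uncertain.

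Alternatives were all barcodes, a stricter cell filter (2000 UMIs, 1000 genes, 15% mitochondrial), no doublet removal, Leiden resolution 0.5, all cells summed, cells weighted equally and thinned cells. Others were TMM scaling, totals without the 20 most abundant genes, pseudocounts of 0.1 and 5, and list minimums of 1 and 50 CPM. After the data had been seen, 5 more were added. These were a gate on the reporter (mCherry at 100 CPM or more in mCherry libraries, under 25 CPM in GFP libraries), leaving out barcodes found in more than 1 library, adding the cluster with endothelial genes, control mCherry as the control of the GFP libraries, and the other reading of the naming rule.

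The steps were tested on simulated data, drawn from the control library of each comparison with 200 genes changed. All 100 planted genes at each of log2 1 and 2 came back with the right sign in each of the 4 comparisons with control, which ran on 4579 genes for mCherry and 4705 for GFP. Intervals held the true value for 95.4% of genes in caMEK1 mCherry, 95.5% in caMKK6 mCherry, 95.5% in caMEK1 GFP and 95.2% in caMKK6 GFP. A list of unchanged genes came out at percentiles 30.5, 21.9, 94.01 and 1.34 in the same order. The software was Python 3.11.15 with scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9, and R 4.3.3.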

Results

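Single-cell 3' RNA sequencing was carried out on hepatocytes from chimeric mice with cells of 2 colours, in which doxycycline induced a transgene. In caMEK1 mice the transgene was constitutively active MEK1, the kinase that activates ERK, as a model of senescence started by an oncogene. In caMKK6 mice it was constitutively active MKK6, which activates the stress kinase p38, as a model of senescence started by stress. Control mice received doxycycline too. Cells were sorted on day 7 into mCherry-positive cells, labelled primary, and GFP-positive cells, labelled surrounding, which gave 6 groups with 1 library each. No group had a replicate, so no difference reported here has a replicate check, and the intervals cover counting error only. The mice were labelled male. Doxycycline was given at 0.2 mg/mL to caMEK1 mice and at 2 mg/mL to caMKK6 and control mice, so the caMEK1 libraries had no control at their own dose.

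The deposited matrices held 1533, 947, 2857, 2887, 4010 and 1769 barcodes in the control mCherry, control GFP, caMEK1 mCherry, caMEK1 GFP, caMKK6 mCherry and caMKK6 GFP libraries. Their totals in the same order were 29131969, 11068352, 98300377, 54389329, 112798072 and 38854094 unique molecular identifiers (UMIs). The sort was gated to enrich hepatocytes. After cell filtering and doublet removal, hepatocyte-like cells were 661 and 504 in the control libraries, 1393 and 893 in the caMEK1 libraries and 3410 and 697 in the caMKK6 libraries, mCherry first. Their shares of the clustered cells were 68.2% (65.2 to 71.1) and 76.5% (73.1 to 79.7) in control, 60.1% (58.04 to 62.1) and 45.5% (43.2 to 47.7) in caMEK1, and 92.4% (91.5 to 93.2) and 47.9% (45.3 to 50.5) in caMKK6, with exact binomial 95% intervals in brackets. The intervals leave out the processing: the control mCherry share was 25.2% under another reading of the cluster naming rule, and the caMKK6 GFP share 78.9% with a stricter cell filter. The UMIs of these cells, summed per library, were the unit of every comparison and ranged from 9756915 in control GFP to 105163919 in caMKK6 mCherry. Median UMIs per hepatocyte-like cell were 42982 and 11491 in control, 62890 and 42282 in caMEK1, and 30862 and 44476 in caMKK6. Control GFP cells were thus the shallowest, and each comparison of a GFP kinase library set deeper cells against them. Cells without a type, of low UMI count, were from 4.63% in caMKK6 mCherry to 37.1% in caMKK6 GFP, and most of the remainder except in caMEK1 GFP, where they were 21.4%.

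The reporter and transgene sequences checked the labels. The sequence of human MKK6 was at 67.98 (66.4 to 69.6) CPM (UMIs scaled to the total of the library's hepatocyte-like sum) in caMKK6 mCherry and 10.5 (9.34 to 11.7) in caMKK6 GFP cells. That of Xenopus MEK1 was at 8.37 (7.76 to 9.01) in caMEK1 mCherry and 0.413 (0.231 to 0.681) in caMEK1 GFP cells. Both were at 0 in the hepatocyte-like cells of the control libraries, which allows up to 0.116 CPM in mCherry and 0.307 CPM in GFP cells. mCherry was at 5659, 1219.8, 351, 11.96, 1335 and 236 CPM in the same order of libraries as above, and EGFP at 0.386, 21.4, 2.47, 18.9, 0.599 and 15.4 CPM. The GFP libraries therefore held mCherry RNA at 1219.8 (control), 11.96 (caMEK1) and 236 CPM (caMKK6). Endogenous Map2k1 (chromosome 9, 64185770 to 64253631, mm10), the mouse MEK1 gene, was at 29.3, 32.9, 17.3, 14.9, 44.2 and 30.02 CPM, and Map2k6 (chromosome 11, 110399122 to 110525522), the mouse MKK6 gene, at 4.36, 3.69, 4.88, 2.07, 2.35 and 2.75 CPM. Xist, which is transcribed from the inactive X chromosome of female cells, was at 213 CPM in control GFP and 8.03 CPM in control mCherry cells, and at most 0.204 CPM in the 4 kinase libraries. The Y-linked gene Ddx3y was at 2.66 CPM in control GFP and between 14.7 and 80.1 CPM in the other libraries. Control GFP thus did not match the male label in Xist and Ddx3y. Control mCherry did not match it fully either, with Xist in 11.5% of cells (2.63% of thinned cells) and 0 UMIs of the Y-linked Eif2s3y. In comparisons with control, sex-biased genes are therefore not separated from genotype. Among the kinase libraries, caMEK1 mCherry had less Ddx3y (14.7 CPM) than caMEK1 GFP (62.6 CPM) and control mCherry cells (18.5 CPM). In cells with mCherry at 100 CPM or more, its log2 fold against control mCherry was -2.00, against -0.31 in all hepatocyte-like cells. Low Ddx3y was thus not limited to control GFP.

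**Figure D1:**
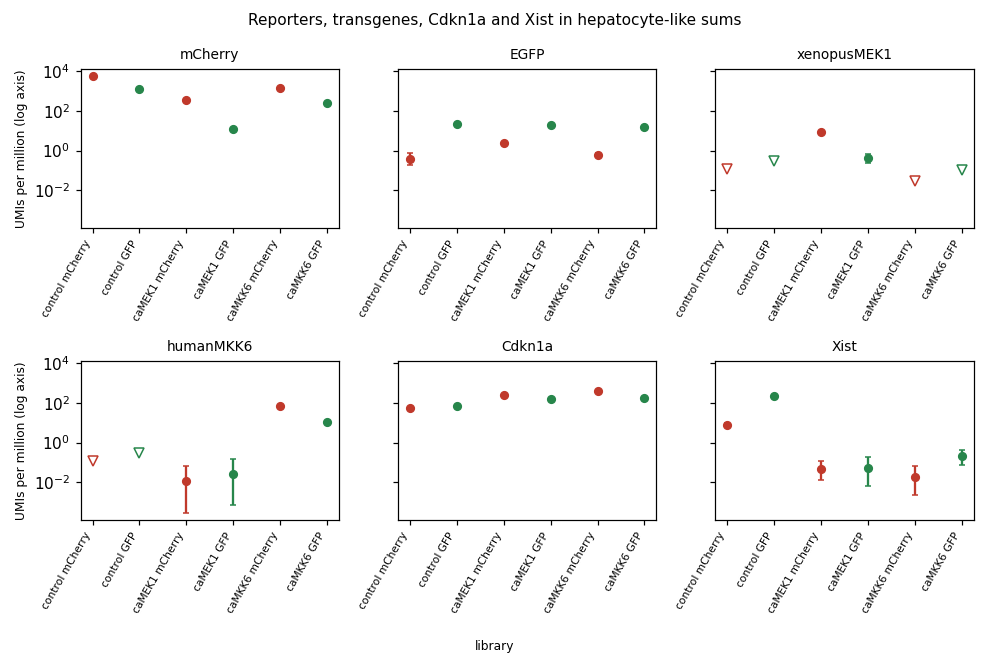
CPM of mCherry, EGFP, the MEK1 and MKK6 transgenes, Cdkn1a and Xist in the hepatocyte-like sum of each library, on a log axis with exact Poisson 95% intervals. Open triangles mark the floor of 3 counts where no UMI was found, red stands for mCherry and green for GFP libraries, and Cdkn1a lies between 53.4 and 376 CPM.

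Cdkn1a, which encodes the cell cycle inhibitor p21 (chromosome 17, 29090976 to 29100727), was higher in all 4 kinase libraries than in control cells of the same colour. In mCherry cells it was higher in caMEK1 (4.78-fold, 4.53 to 5.05) and caMKK6 (7.04-fold, 6.67 to 7.43), and in GFP cells too (2.29-fold, 2.11 to 2.48 and 2.39-fold, 2.20 to 2.59). The range after each fold is its 95% counting interval. In GFP cells with mCherry under 25 CPM the log2 folds were 1.06 in caMEK1 and 0.82 in caMKK6, against 1.18 and 1.24 in all GFP cells. The same limit was set on control GFP cells, of which it left 125 of 504. Both sides of these folds thus changed. With each cell thinned to 2000 UMIs, 10.8% of control mCherry, 36.3% of caMEK1 mCherry and 53.1% of caMKK6 mCherry cells had a Cdkn1a UMI, against 74.3, 97.6 and 97.7% without thinning. In GFP cells the thinned shares were 13.5% in control, 26.6% in caMEK1 and 29.5% in caMKK6, against 54.8, 90.3 and 93.3% without thinning. Thinning left out 14, 38, 6, 24, 56 and 20 cells. As an upper background, since these cells express the gene themselves, unthinned cells with mixed immune markers had a Cdkn1a UMI in 35.7% (caMEK1 mCherry), 31.3% (caMEK1 GFP), 50.00% (caMKK6 mCherry) and 44.1% (caMKK6 GFP) of 28, 83, 8 and 59 cells; the control libraries held 1 and 0 such cells. Their median depths were 22509.5, 15255, 6099.5 and 5392 UMIs, against 62890, 42282, 30862 and 44476 in hepatocyte-like cells. Cdkn2b, which encodes p15, was at 2.90 CPM in caMEK1 mCherry cells and at most 0.138 CPM elsewhere. Cdkn2a, which encodes p16 and p19, had at most 1 UMI in the hepatocyte-like cells of a library, and Mki67, a marker of cycling cells, at most 6.

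In what follows, brackets after a gene give CPM in the first and the second library named, then the fold with its 95% counting interval. A fold against 0 UMIs is a lower bound against a floor of 3 UMIs. Gene lists fixed before the data were examined are described by members at 10 CPM or more in either library. Their medians are log2 folds of CPM plus 1, given with CPM scaling and then after trimmed-mean (TMM) scaling. A percentile places the median among 10000 random lists of similar expression and only describes these libraries. TMM scaling moved the median of all genes at 20 CPM or more from -0.49 to 0.01 in caMEK1 mCherry, from -0.59 to -0.02 in caMEK1 GFP, from -0.04 to 0.19 in caMKK6 mCherry and from -0.20 to 0.01 in caMKK6 GFP, each against control of the same colour. List medians after TMM are thus close to differences from the typical gene except in caMKK6 mCherry, where those with CPM scaling are closer.

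The comparison of caMEK1 mCherry with control mCherry cells asked how primary cells with active MEK1 differed from cells without it. The highest genes were metallothioneins and other genes with few or no UMIs in control cells. Mt4 and Mt3, metallothioneins known from squamous epithelium and from brain, were at 1239.7 and 1121 CPM against 0 UMIs in control, at least 10703-fold and at least 9681-fold higher. They lie beside Mt1 and Mt2 on chromosome 8 (Mt4 from 94137197, Mt1 to 94180327), and Mt1 was also higher (23989.9 against 1343 CPM, 17.9-fold, 17.7 to 18.1). Also among the highest were Ly6d (797 against 0.0386 CPM, 20644-fold, 3705 to 815428), a surface protein of the Ly6 family, and the estrogen sulfotransferase gene Sult1e1 (539 against 0.0772 CPM, 6976-fold, 1931 to 57602). The fetal growth factor gene Igf2 (155 against 0 CPM, at least 1338-fold) and Tff3 (487 against 3.28 CPM, 148-fold, 119.9 to 186), a secreted trefoil factor, followed.

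Genes downstream of ERK were higher as a group in caMEK1 mCherry cells. Of the ERK pathway outputs and feedback regulators, 8 of 11 were at least 2-fold higher and 1 at least 2-fold lower (median 1.82, 2.28 after TMM, percentile 100). They included the ERK phosphatase gene Dusp5 (72.6 against 0.425 CPM, 171-fold, 95.4 to 342), cyclin D1 (Ccnd1 at 216 against 5.60 CPM, 38.6-fold, 32.8 to 45.8) and Ier3 (96.03 against 0.154 CPM, 622-fold, 243 to 2283). Immediate early genes of cell dissociation, which respond to tissue handling and share Egr1 with the ERK list, had a median of 0.72 (1.22 after TMM). Of these, 4 of 12 were at least 2-fold higher and 1 at least 2-fold lower. Of the secretory factors of senescence (SASP), 8 of 13 were at least 2-fold higher and 2 at least 2-fold lower (median 1.59, 2.04 after TMM, percentile 100), with Lcn2 (8187 against 225 CPM, 36.4-fold, 35.5 to 37.3), which encodes lipocalin 2. With members down to 1 CPM this median was 0.79. Of the biliary, progenitor and fetal liver genes, 12 of 16 were at least 2-fold higher and 1 at least 2-fold lower (median 2.52, 2.98 after TMM), among them the fetal albumin relative Afp (87.8 against 2.01 CPM, 43.7-fold, 33.3 to 58.6). Markers of cholangiocytes, which share Sox9 and Spp1 with that list, summed to 109 against 68.1 CPM. Of the extracellular matrix and TGF-beta response genes, 5 of 8 were at least 2-fold higher and 0 at least 2-fold lower (median 2.25, 2.72 after TMM), with Thbs1 (44.8 against 0 CPM, at least 387-fold), and stellate cell markers summed to 21.4 against 4.98 CPM. Of the p53 targets, 6 of 16 were at least 2-fold higher and 1 at least 2-fold lower (median 0.78, 1.26 after TMM with 9 higher and 1 lower). For cell cycle inhibitors and senescence markers the median was 0.55 (1.05 after TMM) over 4 members, and below 0 when members down to 1 CPM were counted.

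Several groups of genes of hepatocyte function were lower in caMEK1 mCherry cells. Car3 (1.03 against 2250.1 CPM, 2188-fold, 1774 to 2733), which encodes carbonic anhydrase 3, and the male-biased P450 gene Cyp4a12a (0.260 against 349.8 CPM, 1345-fold, 888 to 2148) were the lowest. Of the growth hormone and male-biased liver genes, 0 of 16 were at least 2-fold higher and 15 at least 2-fold lower (median -3.71, -3.21 after TMM). Of the bile acid synthesis and transport genes, 0 of 18 were at least 2-fold higher and 15 at least 2-fold lower (median -2.04, -1.54 after TMM with 0 higher and 12 lower, percentile 0), with Slco1a1 (5.02 against 333 CPM, 66.3-fold, 60.1 to 73.2), a bile acid and anion carrier, and Cyp7a1 (0.957 against 37.95 CPM, 39.6-fold, 31.6 to 50.4), the rate-limiting enzyme of bile acid synthesis (chromosome 4, 6265612 to 6275633). Of the cytochrome P450 and conjugation enzymes, 4 of 29 were at least 2-fold higher and 18 at least 2-fold lower (median -1.85, -1.35 after TMM); in cells with mCherry at 100 CPM or more the median was -3.32. Of the fatty acid oxidation and PPARA targets, 0 of 19 were at least 2-fold higher and 15 at least 2-fold lower (median -1.67, -1.17 after TMM with 0 higher and 12 lower), and of the fatty acid synthesis genes, 0 of 14 were at least 2-fold higher and 12 at least 2-fold lower (median -2.12, -1.62 after TMM). Of the urea cycle and amino acid catabolism genes, 0 of 22 were at least 2-fold higher and 12 at least 2-fold lower (median -1.49, -0.98 after TMM). Of the secreted plasma proteins of hepatocytes, however, 9 of 30 were at least 2-fold higher and 1 at least 2-fold lower (median 0.03, 0.54 after TMM with 12 higher and 1 lower), and the hepatocyte markers summed to 148079 against 86211 CPM. Of the acute phase proteins, which the liver secretes in inflammation, 20 of 29 were at least 2-fold higher and 1 at least 2-fold lower (median 1.55, 2.06 after TMM with 23 higher and 0 lower). Interferon response genes had a median of -1.23 (-0.75 after TMM), at percentile 0.160, with 9 of 12 at least 2-fold lower (4 after TMM). The 1393 hepatocyte-like cells came from clusters 1 (1071), 3 (177) and 17 (145), and those of control mCherry mostly from clusters 5 (417) and 16 (239). Cells of clusters 3 and 17, which held most caMEK1 GFP cells, had mCherry at 13.01 and 21.5 CPM in the caMEK1 mCherry library, against 440.0 CPM in cluster 1.

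The comparison of caMKK6 mCherry with control mCherry cells asked the same of primary cells with active MKK6. The highest genes were Cyp17a1 (141 against 0.965 CPM, 146-fold, 99.00 to 226), a steroid hydroxylase gene, the MKK6 transgene itself, the transcription factor gene Klf6 (134 against 1.16 CPM, 115-fold, 80.8 to 171) and Sult1e1 (63.1 against 0.0772 CPM, 817-fold, 226 to 6745). Serpina7 (329 against 5.13 CPM, 64.1-fold, 54.1 to 76.6), which encodes thyroxine-binding globulin, and Lepr (54.4 against 0.154 CPM, 352-fold, 137 to 1293), the leptin receptor, were also among the highest. Cyp3a11, a xenobiotic-metabolising P450 gene that is also among the hepatocyte markers, was at 9932 against 450.5 CPM (22.05-fold, 21.6 to 22.5).

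Genes of the p38 and JNK stress response were higher as a group in caMKK6 mCherry cells. Of these, 8 of 13 were at least 2-fold higher and 1 at least 2-fold lower (median 1.63, 1.86 after TMM, percentile 100). They included Dusp8 (35.8 against 0.270 CPM, 132-fold, 64.2 to 329.7) and Dusp10 (39.1 against 2.28 CPM, 17.2-fold, 13.3 to 22.6), phosphatases that act on p38 and JNK, and the small heat shock protein gene Hspb1 (32.6 against 3.47 CPM, 9.39-fold, 7.62 to 11.7). Of the secretory factors of senescence (SASP), 6 of 13 were at least 2-fold higher and 2 at least 2-fold lower (median 0.83, 1.06 after TMM, percentile 99.99); the median was 0.45 with members down to 1 CPM and below 0 with members at 50 CPM or more alone. They included Lcn2 (912 against 225 CPM, 4.05-fold, 3.95 to 4.16), while the activin subunit gene Inhba (3.55 against 22.4 CPM, 6.32-fold, 5.54 to 7.22) was lower. Of the ERK pathway outputs and feedback regulators, 2 of 8 were at least 2-fold higher and 2 at least 2-fold lower (median 0.67, 0.89 after TMM), again below 0 with members at 50 CPM or more. The ERK-responsive gene Egr1 (52.00 against 203 CPM, 3.91-fold, 3.76 to 4.06) was lower. Of the biliary, progenitor and fetal liver genes, 7 of 11 were at least 2-fold higher and 0 at least 2-fold lower (median 1.54, 1.77 after TMM), with Anxa5 (414 against 38.7 CPM, 10.7-fold, 10.04 to 11.4) and Ly6d (32.5 against 0.0386 CPM, 843-fold, 151 to 33309). The cholangiocyte marker sum was 46.96 against 68.1 CPM. Plaur (24.8 against 0 CPM, at least 214-fold), the urokinase receptor, and Gdf15 (25.7 against 7.03 CPM, 3.66-fold, 3.15 to 4.28), a stress-induced cytokine, were higher too.

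Several groups of genes of liver metabolism were lower in caMKK6 mCherry cells. Of the growth hormone and male-biased liver genes, 1 of 17 were at least 2-fold higher and 12 at least 2-fold lower (median -2.91, -2.68 after TMM). Elovl3 (0.0951 against 219 CPM, 2307-fold, 1253 to 4813), a fatty acid elongase gene, and Car3 (14.4 against 2250.1 CPM, 156-fold, 148 to 164) were the lowest of all. Of the bile acid synthesis and transport genes, 2 of 18 were at least 2-fold higher and 12 at least 2-fold lower (median -1.58, -1.35 after TMM, percentile 0). Cyp8b1 (1.29 against 236 CPM, 183-fold, 154 to 218), which directs synthesis to cholic acid, was lower, and Cyp7a1 (0.0285 against 37.95 CPM, 1330.4-fold, 454 to 6462) was nearly undetected. Of the cholesterol synthesis genes, 0 of 19 were at least 2-fold higher and 16 at least 2-fold lower (median -1.78, -1.55 after TMM), with Idi1 (49.8 against 233 CPM, 4.67-fold, 4.50 to 4.85) and Insig1 (47.9 against 271 CPM, 5.67-fold, 5.47 to 5.88). Of the fatty acid synthesis genes, 1 of 14 were at least 2-fold higher and 12 at least 2-fold lower (median -1.81, -1.58 after TMM), and of the cytochrome P450 and conjugation enzymes, 8 of 30 were at least 2-fold higher and 15 at least 2-fold lower (median -1.01, -0.78 after TMM). Urea cycle and amino acid catabolism genes had a median of -0.03 (0.20 after TMM), gluconeogenesis and glycogen genes one of -0.13 (0.10 after TMM) and nuclear-encoded oxidative phosphorylation genes one of 0.02 (0.25 after TMM). Acute phase proteins had a median of 0.65 (0.88 after TMM) with 11 of 27 at least 2-fold higher. The interferon response median was 0.10 (0.31 after TMM). The hepatocyte-like cells came mostly from clusters 0 (1495), 2 (1024) and 4 (653). Endothelial markers summed to 13.9 against 22.7 CPM.

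Surrounding cells of caMEK1 mice were compared with control GFP cells to ask what neighbours of primary cells expressed. Acute phase proteins made up the group with the highest median of those fixed in advance, leaving aside the sex-linked genes of the label check. Of these, 26 of 29 were at least 2-fold higher and 0 at least 2-fold lower (median 1.99, 2.58 after TMM), with Lcn2 (8202 against 248 CPM, 33.1-fold, 31.8 to 34.5) and the interleukin-1 receptor antagonist gene Il1rn (189 against 2.25 CPM, 83.95-fold, 55.4 to 134). The highest gene was Sult1e1 (270.3 against 0 CPM, at least 879-fold), followed by Mt3 (71.9 against 0 CPM, at least 234-fold), A2m (93.6 against 0.410 CPM, 228-fold, 89.1 to 838) and Mt4 (61.2 against 0 CPM, at least 199-fold). Tff3 (681 against 12.6 CPM, 53.98-fold, 45.2 to 64.98) was higher as well. In cells with mCherry under 25 CPM, in control GFP too, the log2 folds of Mt3, Mt4 and Ly6d were 3.35, 1.96 and 4.55, against 6.19, 5.96 and 5.61 in all hepatocyte-like cells.

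Secretory genes were higher in caMEK1 GFP cells as well. Of the secretory factors of senescence (SASP), 6 of 12 were at least 2-fold higher and 1 at least 2-fold lower (median 0.89, 1.44 after TMM, percentile 100), and the median was 0.45 with members down to 1 CPM. Besides Lcn2, Cxcl1 (146 against 42.02 CPM, 3.48-fold, 3.15 to 3.86), a neutrophil-attracting chemokine gene, was higher. Lcn2 is also on the acute phase list, so these lists are not independent. Neutrophil markers summed to 13.1 against 0.102 CPM and Kupffer cell markers to 14.99 against 0.615 CPM in these sums. The ERK pathway outputs and feedback regulators had a median of -0.09 (0.47 after TMM), on either side of 0 by scaling, although Ccnd1 (110.2 against 17.5 CPM, 6.29-fold, 5.39 to 7.37) was higher. Of the growth hormone and male-biased liver genes, 1 of 17 were at least 2-fold higher and 14 at least 2-fold lower (median -3.18, -2.63 after TMM), with Car3 (1.71 against 3165 CPM, 1853-fold, 1445 to 2417) and Elovl3 (0.744 against 410.4 CPM, 552-fold, 379 to 838) among the lowest genes. Of the bile acid synthesis and transport genes, 0 of 17 were at least 2-fold higher and 10 at least 2-fold lower (median -1.70, -1.12 after TMM, percentile 0.0200). Of the cholesterol synthesis genes, 0 of 19 were at least 2-fold higher and 16 at least 2-fold lower (median -1.37, -0.80 after TMM with 1 higher and 5 lower), and of the fatty acid synthesis genes, 0 of 14 were at least 2-fold higher and 12 at least 2-fold lower (median -2.04, -1.46 after TMM). Of the interferon response genes, 0 of 17 were at least 2-fold higher and 8 at least 2-fold lower (median -0.98, -0.44 after TMM with 0 higher and 4 lower, percentile 0.310), with Rsad2 (0.578 against 13.6 CPM, 23.6-fold, 14.8 to 39.3) and Ifit1 (1.21 against 10.97 CPM, 9.05-fold, 6.31 to 13.2). Xist (0.0551 against 213 CPM, 3875-fold, 1071 to 32019) was among the lowest genes. The caMEK1 GFP cells came mostly from clusters 3 (760) and 17 (104), and those of control GFP from clusters 11 (346), 5 (120) and 16 (38).

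The same comparison in caMKK6 mice gave a higher interferon response in surrounding cells. Of the interferon response genes, 13 of 24 were at least 2-fold higher and 0 at least 2-fold lower (median 1.18, 1.39 after TMM, percentile 100), with Ifi44 (37.2 against 3.07 CPM, 12.1-fold, 8.43 to 18.04), Isg15 (65.1 against 9.33 CPM, 6.98-fold, 5.66 to 8.71) and Usp18 (46.6 against 8.40 CPM, 5.54-fold, 4.43 to 7.01). Of the acute phase proteins, 22 of 28 were at least 2-fold higher and 0 at least 2-fold lower (median 1.36, 1.57 after TMM), led by Orm2 (1170.2 against 77.1 CPM, 15.2-fold, 14.1 to 16.3), Saa2 (24268 against 2086 CPM, 11.6-fold, 11.5 to 11.8) and Lcn2 (2172 against 248 CPM, 8.77-fold, 8.42 to 9.13). Hamp2 (373 against 17.3 CPM, 21.5-fold, 18.5 to 25.2), a hepcidin gene, was among the highest genes, with Lepr (20.9 against 0 CPM, at least 68.1-fold) and Cyp17a1 (44.3 against 1.95 CPM, 22.8-fold, 14.5 to 37.9). Of the secretory factors of senescence (SASP), 3 of 11 were at least 2-fold higher and 0 at least 2-fold lower (median 0.62, 0.83 after TMM, percentile 100), and the median was 0.15 with members down to 1 CPM. The Y-linked Eif2s3y (25.9 against 0 CPM, at least 84.3-fold) and Ddx3y (80.1 against 2.66 CPM, 30.1-fold, 20.5 to 46.1) were the highest of all, and Xist (0.204 against 213 CPM, 1046-fold, 479.9 to 2855) was among the lowest. Kupffer cell markers summed to 5.71 against 0.615 CPM and endothelial markers to 29.4 against 50.9 CPM.

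Some groups of metabolic genes were lower in caMKK6 GFP cells, where Car3 (6.97 against 3165 CPM, 454-fold, 396 to 523) was the lowest gene. Of the growth hormone and male-biased liver genes, 2 of 17 were at least 2-fold higher and 13 at least 2-fold lower (median -3.44, -3.22 after TMM). Of the bile acid synthesis and transport genes, 0 of 18 were at least 2-fold higher and 9 at least 2-fold lower (median -1.01, -0.79 after TMM, percentile 0), with Cyp8b1 (0.578 against 281 CPM, 485-fold, 303 to 835) and Cyp7a1 (0 against 28.8 CPM, at least 282-fold). Of the fatty acid synthesis genes, 1 of 14 were at least 2-fold higher and 8 at least 2-fold lower (median -1.17, -0.95 after TMM), but Scd1 (4435 against 1338 CPM, 3.31-fold, 3.25 to 3.37), the stearoyl-CoA desaturase gene, was higher. Cholesterol synthesis genes had a median of -0.39 (-0.17 after TMM), urea cycle and amino acid catabolism genes one of -0.29 (-0.07 after TMM), gluconeogenesis and glycogen genes one of -0.35 (-0.13 after TMM) and nuclear-encoded oxidative phosphorylation genes one of -0.16 (0.06 after TMM). The p38 and JNK stress response genes had a median of -0.12 (0.09 after TMM) and the ERK pathway outputs and feedback regulators one of -0.09 (0.13 after TMM), both on either side of 0 by scaling. The hepatocyte-like cells came from clusters 8 (331), 13 (218), 4 (79), 0 (38) and 2 (29). Cells of clusters 0, 2 and 4, which held most caMKK6 mCherry cells, had mCherry at 1658, 1714 and 736 CPM in this library. In cells with mCherry under 25 CPM, in control GFP too, the log2 folds of Klf6, Cyp17a1 and Lepr were 1.84, 3.19 and 3.92, against 3.38, 3.94 and 4.46 in all.

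**Figure D2:**
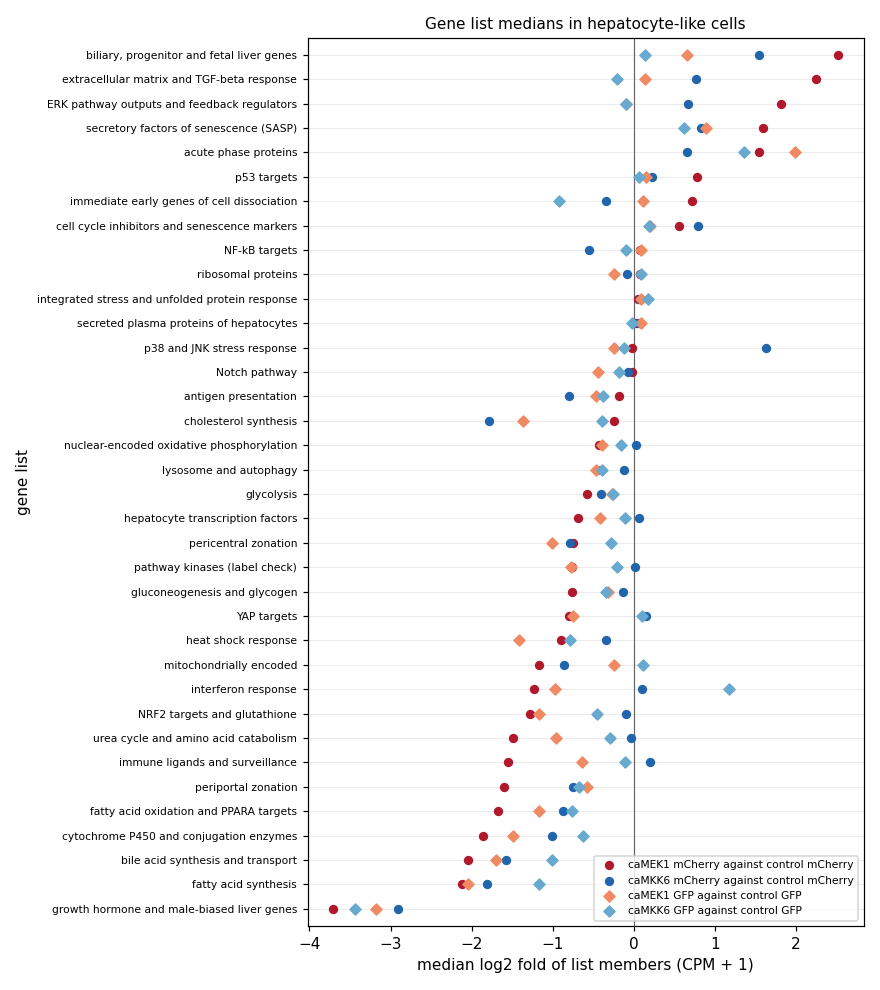
Median log2 fold (CPM plus 1) of each gene list with at least 3 measured members, in the 4 kinase libraries against control of the same colour. Circles are mCherry and diamonds GFP libraries, red shades caMEK1 and blue shades caMKK6; growth hormone and male-biased genes lie lowest in all 4, between -3.71 and -2.91.

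Within each genotype, mCherry cells were compared with GFP cells of the same genotype and dose. Y-linked genes differed between the colours as well. Ddx3y was at 14.7 against 62.6 CPM in caMEK1 and 71.1 against 80.1 CPM in caMKK6. Eif2s3y was at 5.31 against 25.7 CPM and 2.94 against 25.9 CPM. Sex-linked genes had a median of -2.01 in caMEK1 and -0.50 in caMKK6, with 3 and 1 of 3 at least 2-fold lower. With mCherry cells at 100 CPM or more of mCherry and GFP cells under 25 CPM, these medians were -3.75 and -0.58. In caMEK1, Igf2 (155 against 2.15 CPM, 72.1-fold, 57.8 to 91.3) and Afp (87.8 against 5.23 CPM, 16.8-fold, 14.5 to 19.5) were higher in primary cells, as were Mt4 (20.3-fold, 19.4 to 21.1) and Mt3 (15.6-fold, 15.01 to 16.2). With mCherry cells at 100 CPM or more of mCherry (707 of 1393) and GFP cells under 25 CPM, the log2 folds of Igf2, Afp, Mt4 and Mt3 were 6.56, 5.43, 8.76 and 7.18, against 5.63, 3.83, 4.32 and 3.94 in all hepatocyte-like cells. Of the ERK pathway outputs and feedback regulators, 6 of 10 were at least 2-fold higher and 0 at least 2-fold lower (median 1.29, 1.33 after TMM). The periportal P450 gene Cyp2f2 (48.2 against 262 CPM, 5.43-fold, 5.24 to 5.64) and Selenbp2 (26.5 against 128 CPM, 4.83-fold, 4.60 to 5.09) were lower in primary cells. Acute phase proteins were lower too, with a median of -0.52 (-0.49 after TMM). Gdf15 was lower in primary cells (8.12 against 25.3 CPM, 3.12-fold, 2.82 to 3.45).

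In caMKK6, primary cells held more Apoa4 (4566 against 812 CPM, 5.63-fold, 5.55 to 5.70), which encodes an apolipoprotein, and more Dusp8 (35.8 against 6.22 CPM, 5.75-fold, 4.96 to 6.71) and Cidec (25.6 against 3.64 CPM, 7.04-fold, 5.80 to 8.63), a lipid droplet gene. With the same limits on mCherry, their log2 folds were 4.30, 4.34 and 4.08, against 2.49, 2.35 and 2.52 in all hepatocyte-like cells. The p38 and JNK stress response genes had a median of 1.16 (1.28 after TMM). Hamp2 (chromosome 7, 30922372 to 30924681, 16.9-fold, 16.1 to 17.7), Saa2 (7.76-fold, 7.72 to 7.79) and Saa1 (7.26-fold, 7.23 to 7.30) were lower in primary cells, and acute phase proteins had a median of -0.89 (-0.77 after TMM). Of the cholesterol synthesis genes, 0 of 19 were at least 2-fold higher and 17 at least 2-fold lower (median -2.50, -2.38 after TMM). Of the interferon response genes, 0 of 23 were at least 2-fold higher and 16 at least 2-fold lower (median -1.49, -1.37 after TMM), with Rsad2 (3.66 against 26.2 CPM, 7.16-fold, 6.33 to 8.11).

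The 2 control libraries were compared to see how far colours differed without an active kinase. However, 81.2% of the 504 control GFP cells had an mCherry UMI (60.1% of 466 thinned cells), and 125 were under 25 CPM of mCherry. Over 4830 genes the log2 folds had a standard deviation of 0.27, against 1.30 in caMEK1 mCherry, 1.08 in caMKK6 mCherry, 1.00 in caMEK1 GFP and 0.79 in caMKK6 GFP against control. The 0.27 comes from 2 sorts of control cells at the same dose. The other values also hold differences between mice of different groups, and in caMEK1 in dose, so 0.27 is no measure of their background. Cyp2a4 (33.1 against 10.2 CPM, 3.23-fold, 2.62 to 4.01) and Hsd17b6 (122 against 55.4 CPM, 2.21-fold, 2.01 to 2.42), both genes of steroid metabolism, were among the genes higher in control mCherry cells; Hsd17b6 was lower there under another reading of the cluster naming rule, which left fewer control cells in the hepatocyte-like class. Xist (26.6-fold, 23.04 to 30.8) and urinary protein genes such as Mup7 (226 against 829 CPM, 3.66-fold, 3.54 to 3.79) and Mup20 (2798 against 7731 CPM, 2.76-fold, 2.73 to 2.79) were lower there. Of the cholesterol synthesis genes, 0 of 19 were at least 2-fold higher and 7 at least 2-fold lower (median -0.89, -0.78 after TMM). Acute phase proteins had a median of -0.12 (-0.01 after TMM), secretory factors of senescence (SASP) one of -0.15 (-0.04 after TMM) and interferon response genes one of -0.17 (-0.07 after TMM).

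The comparison of the kinases asked how senescence started by an oncogene differed from that started by stress, first in primary cells. In caMEK1 mCherry relative to caMKK6 mCherry cells, Ccnd1 (216 against 0.618 CPM, 350.0-fold, 274 to 454), Dusp5 (72.6 against 0.247 CPM, 293-fold, 200.1 to 449.6), Mt4 (9312-fold, 5549.7 to 17033) and Il1rn (281 against 1.26 CPM, 224-fold, 188 to 267) were higher. Gstm3 (586-fold, 430.1 to 820.3), Cyp3a11 (60.6-fold, 59.6 to 61.7) and Hspb1 (0.685 against 32.6 CPM, 47.6-fold, 36.7 to 62.9) were lower. The ERK pathway outputs and feedback regulators had a median of 1.25 (1.53 after TMM), the p38 and JNK stress response genes one of -1.44 (-1.20 after TMM) and cholesterol synthesis genes one of 1.56 (1.83 after TMM). Among surrounding cells, Tff3 (681 against 10.3 CPM, 65.8-fold, 58.8 to 73.96), Cyp8b1 (52.5 against 0.578 CPM, 90.8-fold, 56.6 to 156) and Ccnd1 (110.2 against 5.71 CPM, 19.3-fold, 16.5 to 22.6) were higher in caMEK1, and Hamp2 (145-fold, 119 to 180.4), Scd1 (21.9-fold, 21.4 to 22.5) and Ifit1 (1.21 against 54.4 CPM, 44.9-fold, 33.3 to 62.03) were lower. Of the interferon response genes, 0 of 23 were at least 2-fold higher and 23 at least 2-fold lower (median -2.55, -2.23 after TMM with 0 higher and 18 lower). The doxycycline dose differed between these libraries.

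Fold changes against control were compared across genes at 20 CPM or more, which are not independent replicates, in 4 pairs of comparisons. Primary and surrounding cells had a Pearson r of 0.88 (Spearman 0.83) in caMEK1 over 5113 genes and 0.81 (0.74) in caMKK6 over 5282 genes. Both colours of a genotype shared its group of mice and its dose, and both control sorts came from control mice. Differences between mice of different groups, and in caMEK1 in dose, can therefore enter both comparisons and raise r. The sums behind these values were not gated on mCherry. In caMEK1 mCherry, 177 and 145 cells lay in clusters 3 and 17, which held most caMEK1 GFP cells. In caMKK6 GFP, 38, 29 and 79 cells lay in clusters 0, 2 and 4, which held most caMKK6 mCherry cells. EGFP in the caMEK1 mCherry library was at 18.4 and 3.28 CPM in clusters 3 and 17, against 0.374 CPM in cluster 1. Human MKK6 in the caMKK6 GFP library was at 67.5, 90.4 and 22.4 CPM in clusters 0, 2 and 4. Mixing of the colours therefore enters both values of r, by an amount that was not measured. Primary cells of the kinases, compared with the same control library, had an r of 0.64 (0.60), and surrounding cells one of 0.75 (0.72). A shared control alone gave simulated unchanged libraries an r of 0.78 and 0.77. The covariances, however, were 0.889 and 0.579, against 0.00219 and 0.00497 simulated. With control cells split at random between the comparisons, r was 0.64 and 0.73. The simulation holds counting error only, so differences of the shared control library from other control mice still enter both comparisons.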

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

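All tests in this part were chosen only after the results they concern had been seen. The interferon response list went opposite ways in the surrounding cells of the kinases. Its median against control GFP was -0.98 (-0.44 after TMM) in caMEK1 GFP and 1.18 (1.39 after TMM) in caMKK6 GFP cells. With 1 library per group the difference between them was not tested.

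Human MKK6 RNA turned up where no such transgene was labelled: 38 UMIs in the caMEK1 mCherry and 37 in the caMEK1 GFP library, counted over every barcode. These libraries also shared 465 barcodes, 186 of near-equal depth in both and 276 with under 5% of the UMIs of one copy in the other, while any other pair of libraries shared at most 4. Free RNA in the caMEK1 cell suspensions would have spread the sequence over barcodes by depth, which puts 74.5 UMIs outside the 186 barcodes of near-equal depth, but 3 lay there. These barcodes held 96% (88.8 to 99.2) of the human MKK6 UMIs, which is consistent with sequences of a library outside these 6 assigned to both caMEK1 libraries. That source stays a hypothesis, no biological explanation was tested, and 2 of these barcodes in mCherry and 1 in GFP were among the hepatocyte-like cells, of which 1210 of 1393 and 824 of 893 were left without any shared barcode.

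Several genes stood among the highest in both the primary and the surrounding cells of a genotype, so carried-over primary cells or their RNA were weighed as the source of the excess over control GFP. Acute phase proteins were lower in primary than in surrounding cells, with medians of -0.52 in caMEK1 and -0.89 in caMKK6, which argues against carry-over as their source. The higher of the upper bounds from mCherry and the transgene allows a carry-over of at most 7.47% of the mCherry level in caMEK1, from the transgene, and 18.2% in caMKK6, while mCherry alone gives 3.40% (3.11 to 3.71) in caMEK1. The excess of Tff3 (137%), Il1rn (66.6%) and Sult1e1 (50.2%) in caMEK1 and of Lepr (38.5%), Serpina7 (32.1%) and Cyp17a1 (30.04%) in caMKK6 lay above these limits. The limits concern carry-over as the whole of the excess, not as a part of it. Cells with little mCherry kept 100.4, 96.1 and 94.1% of it in caMEK1, in the order named. In caMKK6 they kept 67.4, 65.9 and 61.3%. The excess of Mt3 (6.41%) and Mt4 (4.94%) lay below the limit, the intervals of Ly6d (7.21%, 6.91 to 7.52) and Klf6 (18.5%, 17.2 to 20.04) held the limit, all 3 caMEK1 genes lay above mCherry alone, and cells with little mCherry kept 12.8, 4.70, 38.98 and 24.1% of it, so for these 4 genes carry-over stays a candidate source beside a response of surrounding cells.

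Cells outside the hepatocyte-like class differed from control of the same colour. Kupffer cell or macrophage-like cells were 3.06% of caMEK1 mCherry and 15.99% of caMEK1 GFP cells (median 2130 UMIs), against 0 in both control libraries. The 314 in caMEK1 GFP all came from cluster 12, which had 0.147 of the library median UMI count. It scored higher for neutrophil (1.30) than for Kupffer cell markers (1.03), but only 2 neutrophil markers were detected. All 12 hepatocyte markers were detected there beside 9 Kupffer cell markers, and Marco was the only Kupffer cell marker among its 10 leading genes. An unnamed cluster with hepatocyte and endothelial genes held 1.38% of caMEK1 mCherry and 9.62% of caMEK1 GFP cells, again against 0. Unnamed cells with mixed immune markers were 1.21% of caMEK1 mCherry, 4.23% of caMEK1 GFP and 4.05% of caMKK6 GFP cells, against 0.103% of control mCherry and 0 of control GFP cells. In caMKK6 GFP, unnamed cells with endothelial and stellate markers were 10.9% against 1.37% in control GFP. Unnamed cells of low UMI count were 37.1% of caMKK6 GFP against 22.2% of control GFP cells, but 4.63% of caMKK6 mCherry against 31.1% of control mCherry cells. The sort was gated to enrich hepatocytes, and these shares can depend on it.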

How the results depend on the processing

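Of 168 list medians, 91 were at least 0.5 from 0, and 78 of these kept their direction under each alternative run while 13 turned under at least 1. Of 107 such folds of named genes, 106 kept their direction and 1 turned. Over all list medians, 1869 of 2923 values under an alternative stayed within the resampling interval of the reported one. The sign was the other one for 143 values, 130 of them of medians under 0.5 from 0. Of 1639 values of single-gene folds, 988 lay inside, 650 moved outside without turning and 1 turned. Shares of cells with a UMI moved without thinning for 32 of 42. No model of genotype plus colour, which would take their interaction as noise, was fitted. Depth limited genes near 0 in control GFP, where 3 UMIs are 0.307 CPM. All alternatives were planned except the reporter gate, the removal of shared barcodes, the endothelial-marker cluster, control mCherry as control of the GFP libraries and the other reading of the naming rule, which were chosen after seeing the data.

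The values below are those that moved for the main lists or turned for any list. The lists are secretory factors of senescence (SASP), ERK pathway outputs and feedback regulators, p38 and JNK stress response, bile acid synthesis and transport, interferon response, cell cycle inhibitors and senescence markers, cell cycle, DNA replication and mitosis, extracellular matrix and TGF-beta response, periportal zonation, YAP targets, NF-kB targets and sex-linked genes (label check). With members down to 1 CPM, the median of senescence markers was -0.24 (caMEK1 mCherry), that of SASP 0.79 (caMEK1 mCherry), 0.45 (caMKK6 mCherry), 0.45 (caMEK1 GFP), 0.15 (caMKK6 GFP), that of ERK 1.24 (caMEK1 mCherry), that of cell cycle -0.20 (caMEK1 mCherry), that of p38 and JNK 1.12 (caMKK6 mCherry), that of matrix -0.0661 (caMKK6 mCherry) and that of bile acid -1.56 (caMEK1 GFP). With TMM, the median of SASP was 2.04 (caMEK1 mCherry), 1.06 (caMKK6 mCherry), 1.44 (caMEK1 GFP), that of ERK 2.28 (caMEK1 mCherry), that of bile acid -1.54 (caMEK1 mCherry), -1.35 (caMKK6 mCherry), -1.12 (caMEK1 GFP), -0.79 (caMKK6 GFP), that of p38 and JNK 1.86 (caMKK6 mCherry), that of periportal 0.00686 (caMEK1 GFP) and that of interferon -0.44 (caMEK1 GFP), 1.39 (caMKK6 GFP). Without the 20 most abundant genes, the median of SASP was 1.91 (caMEK1 mCherry), 1.28 (caMEK1 GFP), that of ERK 2.15 (caMEK1 mCherry), that of bile acid -1.77 (caMEK1 mCherry), -1.32 (caMEK1 GFP), -0.84 (caMKK6 GFP) and that of interferon -0.64 (caMEK1 GFP), 1.36 (caMKK6 GFP). With pseudocount 0.1, the median of SASP was 1.76 (caMEK1 mCherry). With pseudocount 5, the median of SASP was 1.20 (caMEK1 mCherry), 0.71 (caMEK1 GFP), that of ERK 1.33 (caMEK1 mCherry), that of bile acid -1.96 (caMEK1 mCherry), -1.55 (caMKK6 mCherry), that of p38 and JNK 1.36 (caMKK6 mCherry) and that of interferon -0.85 (caMEK1 GFP), 1.03 (caMKK6 GFP). With members at 50 CPM or more, the median of SASP was 1.32 (caMEK1 mCherry), -0.37 (caMKK6 mCherry), 1.45 (caMEK1 GFP), that of ERK 2.05 (caMEK1 mCherry), -1.29 (caMKK6 mCherry), that of YAP 0.72 (caMEK1 mCherry), that of p38 and JNK 0.96 (caMKK6 mCherry), that of interferon -1.44 (caMEK1 GFP), that of sex-linked -1.78 (caMEK1 GFP), -1.50 (caMKK6 GFP) and that of bile acid -1.11 (caMKK6 GFP). With the reporter gate, the median of ERK was 2.13 (caMEK1 mCherry), that of bile acid -2.60 (caMEK1 mCherry), -1.63 (caMKK6 mCherry), -1.47 (caMEK1 GFP), -0.74 (caMKK6 GFP) and that of p38 and JNK 1.70 (caMKK6 mCherry). With the other reading of the naming rule, the median of ERK was 1.51 (caMEK1 mCherry), that of bile acid -2.45 (caMEK1 mCherry), -1.66 (caMKK6 mCherry), -2.21 (caMEK1 GFP), that of periportal 0.26 (caMEK1 mCherry), 0.92 (caMKK6 mCherry), 0.18 (caMKK6 GFP), that of p38 and JNK 1.50 (caMKK6 mCherry) and that of interferon 0.97 (caMKK6 GFP). With the stricter cell filter, the median of bile acid was -2.11 (caMEK1 mCherry), -1.08 (caMKK6 GFP). With cells weighted equally, the median of bile acid was -2.08 (caMEK1 mCherry), that of SASP 0.95 (caMKK6 mCherry), 1.08 (caMEK1 GFP) and that of interferon -1.13 (caMEK1 GFP). Without shared barcodes, the median of bile acid was -2.12 (caMEK1 mCherry), -1.81 (caMEK1 GFP). With all cells, the median of bile acid was -1.55 (caMKK6 mCherry), -1.10 (caMKK6 GFP), that of SASP 1.28 (caMEK1 GFP) and that of interferon -0.90 (caMEK1 GFP). With thinned cells, the median of bile acid was -1.53 (caMKK6 mCherry), that of NF-kB 0.0522 (caMKK6 mCherry), that of SASP 1.25 (caMEK1 GFP), 0.90 (caMKK6 GFP) and that of interferon -1.28 (caMEK1 GFP), 1.03 (caMKK6 GFP). With control mCherry as control of the GFP libraries, the median of SASP was 1.12 (caMEK1 GFP), 1.00 (caMKK6 GFP), that of bile acid -1.51 (caMEK1 GFP), -0.94 (caMKK6 GFP) and that of interferon -0.80 (caMEK1 GFP), 1.41 (caMKK6 GFP). With the endothelial-marker cluster, the median of bile acid was -1.65 (caMEK1 GFP). Turned medians were 13 of these, and the cause was not tested, except that the 1 and 50 CPM minimums count other members.

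With all barcodes, hepatocyte-like shares were 44.6% (control mCherry), 52.9% (control GFP), 64.6% (caMEK1 mCherry), 88.9% (caMKK6 mCherry), 41.6% (caMKK6 GFP). With the stricter cell filter, hepatocyte-like shares were 83.9% (control mCherry), 91.5% (control GFP), 80.7% (caMEK1 mCherry), 59.7% (caMEK1 GFP), 95.3% (caMKK6 mCherry), 78.9% (caMKK6 GFP). With the other reading of the naming rule, hepatocyte-like shares were 25.2% (control mCherry), 58.3% (control GFP). Without doublet removal, hepatocyte-like shares were 63.2% (caMEK1 mCherry). With genes at 5 CPM or more, Pearson r was 0.85, 0.78, 0.62 and 0.74. With genes at 100 CPM or more, Pearson r was 0.91, 0.85, 0.68 and 0.80. The order for r is primary with surrounding cells in caMEK1 and in caMKK6, then the kinases in primary and in surrounding cells. The cause was not tested.

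Folds of single genes that turned follow. With the other reading of the naming rule, log2 folds were -0.28 for Hsd17b6 (control mCherry against control GFP). The cause was not tested.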

Other observations

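Further gene groups are given here as medians of log2 folds against control of the same colour. The order is caMEK1 mCherry, caMKK6 mCherry, caMEK1 GFP and caMKK6 GFP, and signs that differ between the scalings have no direction that holds under both. Heat shock response genes, which encode chaperones, had medians below 0 in all 4 under both scalings, at -0.89, -0.34, -1.41 and -0.79 (-0.40, -0.11, -0.83 and -0.57 after TMM), but in caMKK6 mCherry 2 of 9 members were at least 2-fold higher and 2 at least 2-fold lower. NRF2 targets and glutathione genes were at -1.28, -0.10, -1.17 and -0.45 (-0.78, 0.13, -0.59 and -0.23 after TMM), with 4 of 14 members at least 2-fold lower and 1 higher in caMKK6 GFP. Pericentral zonation genes had medians below 0 throughout, at -0.75, -0.79, -1.01 and -0.28 (-0.24, -0.57, -0.46 and -0.06 after TMM). With the reporter gate their caMEK1 mCherry median was -1.83, and against caMEK1 GFP it was -1.36 with and 0.16 without the gate. Periportal zonation genes were at -1.60, -0.75, -0.57 and -0.68 (-1.09, -0.52, 0.01 and -0.46 after TMM), but at 0.26, 0.92, -0.14 and 0.18 under the other reading of the naming rule. Immediate early genes of cell dissociation, which respond to tissue handling, were at 0.72, -0.35, 0.11 and -0.92 (1.22, -0.12, 0.70 and -0.70 after TMM). Members went both ways, with 3 of 12 at least 2-fold higher and 3 at least 2-fold lower in caMEK1 GFP and 4 of 13 and 4 in caMKK6 mCherry, and with the reporter gate the caMEK1 GFP median was -0.03.

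Mitochondrially encoded genes were at -1.17, -0.86, -0.25 and 0.12 (-0.66, -0.63, 0.34 and 0.34 after TMM), with 7 of 13 members at least 2-fold lower in caMEK1 mCherry and 4 in caMKK6 mCherry (2 and 1 after TMM). In control mCherry against control GFP cells they were at 0.63 (0.74 after TMM). Nuclear-encoded oxidative phosphorylation genes were at -0.43, 0.02, -0.39 and -0.16 (0.08, 0.25, 0.19 and 0.06 after TMM). Urea cycle and amino acid catabolism genes were at -1.49, -0.03, -0.96 and -0.29 (-0.98, 0.20, -0.37 and -0.07 after TMM), and fatty acid oxidation and PPARA targets at -1.67, -0.88, -1.16 and -0.76 (-1.17, -0.65, -0.58 and -0.54 after TMM). Cholesterol synthesis genes were at -0.24, -1.78, -1.37 and -0.39 (0.26, -1.55, -0.80 and -0.17 after TMM). Gluconeogenesis and glycogen genes were at -0.76, -0.13, -0.32 and -0.35 (-0.27, 0.10, 0.26 and -0.13 after TMM) and glycolysis genes at -0.57, -0.41, -0.27 and -0.26 (-0.06, -0.18, 0.30 and -0.05 after TMM). Cytochrome P450 and conjugation enzymes had medians below 0 throughout, at -1.85, -1.01, -1.49 and -0.63 (-1.35, -0.78, -0.91 and -0.41 after TMM). Hepatocyte transcription factors were at -0.68, 0.07, -0.41 and -0.10 (-0.18, 0.29, 0.15 and 0.12 after TMM) and secreted plasma proteins of hepatocytes at 0.03, 0.06, 0.09 and -0.02 (0.54, 0.29, 0.68 and 0.20 after TMM).

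Of the groups tied to senescence and immunity, cell cycle inhibitors and senescence markers were at 0.55, 0.79, 0.20 and 0.19 (1.05, 1.01, 0.77 and 0.40 after TMM) and p53 targets at 0.78, 0.23, 0.15 and 0.07 (1.26, 0.45, 0.73 and 0.28 after TMM). With members down to 1 CPM the former were at -0.24, 0.37, -0.23 and -0.05. Biliary, progenitor and fetal liver genes were at 2.52, 1.54, 0.65 and 0.14 (2.98, 1.77, 1.22 and 0.35 after TMM), and p38 and JNK stress response genes at -0.02, 1.63, -0.25 and -0.12 (0.49, 1.86, 0.29 and 0.09 after TMM). Cholangiocyte markers, which share genes with the biliary list, summed to 157 CPM in caMEK1 GFP against 84.5 CPM in control GFP cells. Extracellular matrix and TGF-beta response genes were at 2.25, 0.77, 0.13 and -0.21 (2.72, 1.00, 0.70 and -0.00315 after TMM), and in caMKK6 mCherry at -0.07 with members down to 1 CPM. NF-kB targets were at 0.08, -0.55, 0.10 and -0.10 (0.58, -0.33, 0.66 and 0.11 after TMM), and in caMKK6 mCherry at 0.05 with thinned cells. Antigen presentation genes were at -0.18, -0.80, -0.46 and -0.38 (0.32, -0.57, 0.12 and -0.16 after TMM) and immune ligands and surveillance genes at -1.55, 0.21, -0.64 and -0.10 (-1.08, 0.43, -0.06 and 0.11 after TMM). Integrated stress and unfolded protein response genes were at 0.05, 0.08, 0.09 and 0.18 (0.56, 0.31, 0.68 and 0.40 after TMM), and lysosome and autophagy genes at -0.45, -0.12, -0.47 and -0.39 (0.05, 0.10, 0.12 and -0.17 after TMM). Notch pathway genes were at -0.03, -0.07, -0.44 and -0.18 (0.44, 0.16, 0.10 and 0.02 after TMM) and YAP targets at -0.79, 0.15, -0.74 and 0.10 (-0.33, 0.36, -0.21 and 0.31 after TMM). The YAP median of caMEK1 mCherry rests on 4 members and was 0.72 with members at 50 CPM or more. Cell cycle, DNA replication and mitosis genes had at most 2 measured members per comparison and were at 1.08, 0.67, -0.98 and -0.19 (1.51, 0.88, -0.42 and 0.03 after TMM), and at -0.20 in caMEK1 mCherry with members down to 1 CPM. Ribosomal proteins, a list that also takes kinases and pseudogenes named after them, were at 0.08, -0.08, -0.24 and 0.08 (0.59, 0.15, 0.34 and 0.31 after TMM).

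The sex-linked genes of the label check, Xist and 4 Y-linked genes, were at -0.31, 2.16, 3.69 and 4.09 (0.17, 2.34, 4.09 and 4.13 after TMM), with 1 to 4 measured members. With members at 50 CPM or more they were at -1.78 in caMEK1 GFP and -1.50 in caMKK6 GFP. Xist was lower and Y-linked genes were higher there. In caMEK1 mCherry, where Ddx3y was the only measured member, the reporter gate gave -2.00. The pathway kinases of the label check were at -0.76, 0.01, -0.78 and -0.20 (-0.27, 0.23, -0.22 and 0.01 after TMM). Eif2s3y, which is Y-linked, was at 0, 0, 5.31, 25.7, 2.94 and 25.9 CPM in the order of libraries of the report. Stab2, an endothelial gene, was at 3.98, 6.66, 22.6, 45.9, 1.56 and 3.16 CPM in the same order. Hemoglobin and other erythroid markers summed to 55.6, 81.8, 0.733, 1.43, 4.76 and 5.98 CPM.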
